A study of Mus musculus with 6 samples.

How the data were processed

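Nuclear RNA from cerebellar granule cells of mice aged 7 months was sequenced in 6 libraries, 3 labelled as homozygous wild type for Ezh1 (WT) and 3 as homozygous conditional knockout (cKO), all carrying Neurod1-Cre. Per the labels' protocols, nuclei were pelleted through an iodixanol cushion, fixed in formaldehyde, stained for the neuronal nuclear antigen NeuN and sorted, RNA was purified with a kit made for fixed tissue, and libraries were built with the NEBNext Ultra II RNA kit. Nuclear RNA holds unspliced and chromatin-retained transcripts, so a gene's level here is not its cytoplasmic mRNA level.

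The authors deposited a single table of whole-number counts per gene, not normalized, with 1 column per library. Per the submitters' processing notes, reads were handled with Subread against the mm10 mouse genome. The version, the gene annotation, the treatment of reads that map to several places and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, nor reads of near-identical copies. The table names genes by NCBI gene identifiers. Of its 24594 entries, 24570 matched a gene of the RefSeq annotation of GRCm38.p6, the assembly that mm10 is drawn from, and 24 did not. Symbols, positions and spans are from that annotation. Each library held between 6340236 and 8284768 counts, and 3920 entries had none. The unmatched entry with identifier 100861531 alone took 26.0% of all counts (24.5% to 26.8% of a library). Malat1, a nuclear long noncoding RNA, took 4.43%, Mir6236 2.30% and Lars2 2.16%, and these 4 entries together held 32.7% to 35.8% of each library. They stayed in the library sizes of the main analysis. None of the 13 mitochondrially encoded mRNAs on the list fixed for them matched an entry, and they were not analysed here.

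Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 13115 genes and 99.8% of all counts. Libraries were scaled by TMM factors (0.982 to 1.02), and each gene was tested for genotype with robust quasi-likelihood fits (glmQLFit and glmQLFTest) over all 6 libraries with no other term. All adjusted p-values of single genes are Benjamini-Hochberg values of this two-sided edgeR test unless another tool is named, and a gene was called higher or lower where it was below 0.05. Levels in CPM are the deposited counts scaled to 1e+06 counts of a library, from its total and its TMM factor. Levels are means ± SD of the 3 libraries of a genotype, log2 fold changes are cKO over WT with their standard errors (SE), and intervals are 95% intervals from the same fit. A gene whose whole interval lay between log2 values of -1 and 1 was counted as within 2-fold. Values of single measures were compared by an exact two-sided permutation test, which with 3 libraries against 3 cannot go below p = 0.1.

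Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 27 lists were subunits of Polycomb repressive complexes PRC2 and PRC1, enzymes of H3K27, H3K36 and H3K4, Hox genes, developmental transcription factors that are classic Polycomb targets, cell cycle inhibitors and senescence genes, mature granule cell markers, granule cell progenitor and immature neuron genes, immediate early genes, ionotropic glutamate and GABA-A receptor subunits, voltage-gated ion channels, clustered protocadherins, imprinted genes, stress and heat shock genes, interferon-stimulated genes, cytosolic ribosomal protein genes, nuclear long noncoding RNAs, sex-linked genes, mitochondrially encoded mRNAs, and markers of Purkinje cells, inhibitory interneurons, unipolar brush cells, astrocytes and Bergmann glia, oligodendrocytes, microglia, vessels with meninges and choroid plexus, and photoreceptors with forebrain neurons. The 25 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2, preset correlation of 0.01 between genes), again with an estimated correlation, and with fry, and p-values were adjusted over the lists. Calls within each list were also counted adjusted over the list alone. Hox genes and developmental transcription factors were also summed per library, which keeps members below the filter. Silent genes were those below a mean of 0.1 CPM in a genotype, and a gain or loss needed at least 0.5 CPM in each library of the other.

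The text names Ezh1 and all tested PRC2 subunits. It names the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 1 CPM and with every cKO library beyond every WT library in the direction of the change, passing over predicted gene models. From each list it names up to 4 called members by smallest p or, with none called, the 2 members of smallest p. Some genes that this rule picks are not reported here. Other genes named below were chosen after their values were seen, and this is said there.

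The analysis was tested on simulated counts for the 13115 genes of this comparison, drawn from the real means and library sizes. It recovered 15.6% of genes changed 1.3-fold, 53.2% of those changed 1.5-fold, 80.4% of those changed 2-fold and 98% of those changed 4-fold. Of the calls, 7.49% were false, and simulations with no change gave 1 call on average. For the changed genes, 94.3% of the 95% intervals held the true value. This was not measured for unchanged genes. Camera found a simulated list of 30 genes shifted by 0.3 in 20 of 20 runs and an unshifted one in 0 of 20. The simulated genes were drawn independently, so these runs do not show how the list test behaves where genes of a list vary together. The alternatives tried were RLE size factors, library size alone, other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, the level of Y-linked genes as a covariate, a looser threshold, and leaving out each library in turn. DESeq2's independent filtering gave no adjusted p to genes of low level, such as Tubg2 (19.8 CPM in WT, 11.3 in cKO), and so could not call them. A lack of DESeq2 calls in a list therefore says nothing about members at such levels. Leaving out the 4 entries with the most counts, and leaving out chromosome 11, were added after the data had been seen.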

Results

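The data were nuclear RNA-seq counts from sorted NeuN-positive nuclei of the mouse cerebellum, of which granule cells, the small excitatory neurons of the cerebellar cortex, are by far the most common kind. The groups were 3 libraries from Ezh1 WT mice and 3 from Ezh1 cKO mice, all aged 7 months and all with Neurod1-Cre, a Cre recombinase named for a transcription factor of granule neurons. Ezh1 encodes a catalytic subunit of PRC2, the Polycomb complex that methylates lysine 27 of histone H3 (H3K27me3), a mark of repressed genes. The single comparison of the design asks, in the words of the study's subject, whether neurons that no longer divide need this mark to be kept up over the long term for the regulation of their genes.

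WT libraries 1, 2 and 3 held 6682805, 7311290 and 8284768 counts, and cKO libraries 1, 2 and 3 held 6827022, 6340236 and 6530793. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may in part be technical. Every pair of libraries of a genotype differed beyond sampling noise (chi-square per degree of freedom of 4.03 to 5.01 over 13096 genes). Replicate 1 of each genotype had Xist, the RNA of the inactive X chromosome, at 811 CPM (WT) and 831 CPM (cKO), with 4 Y-linked genes at 1.51 and 2.45 CPM in sum. The other libraries had Xist between 1.39 and 4.46 CPM and these Y-linked genes between 123 and 148 CPM. Each genotype thus held 1 library of the former kind. Within a genotype, replicate 1 therefore cannot come from the same animal as replicates 2 and 3, and the spread there includes a difference between animals. Whether replicates 2 and 3 came from separate animals is not shown. On the principal component with the most variance (28.4%), WT replicates 2 and 3 lay at -28.35 and -15.55, WT replicate 1 at 3.30, cKO replicates 1 and 3 at 27.3 and 11.8, and cKO replicate 2 beside WT replicate 1.

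Ezh1 itself (NCBI gene 14055; chromosome 11, 101191115 to 101226463, GRCm38) was lower in every cKO library than in every WT library. Its level was 76.7 ± 6.19 CPM in WT and 53.0 ± 2.34 CPM in cKO (470, 543 and 686 counts against 365, 330 and 361), which is 30.8% lower. The log2 fold change was -0.53 (SE 0.10, adjusted p = 0.00672), and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The labels do not say which part of the gene was deleted, and a count over the whole gene also takes in transcripts of the exons left in place, so the remaining counts do not measure intact Ezh1. Without WT replicate 3 the log2 fold change was -0.47 (adjusted p = 0.115), and without cKO replicate 1 it was -0.53 (adjusted p = 0.0833).

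Among single genes, the protocadherin gene Pcdh7, which encodes a cell adhesion protein, was by far the most different, at 170 ± 11.8 CPM in cKO against 23.5 ± 4.22 CPM in WT (7.19-fold, log2 fold change 2.85, SE 0.11, adjusted p = 3.52e-16). It lies on chromosome 5 (57716145 to 58133236) and overlaps the long noncoding RNA gene 4932441J04Rik, which had 1, 2 and 2 counts in the WT libraries and 6, 10 and 5 in the cKO libraries. Neurod1 (chromosome 2, 79452637 to 79456636), a transcription factor of granule neuron differentiation, was 2.16-fold higher, at 307 ± 17.7 against 142 ± 10.4 CPM (log2 fold change 1.11, SE 0.08, adjusted p = 8.03e-10). Both genotypes carry Neurod1-Cre, and the labels do not say how the Cre was placed in the genome or in how many copies. Rapgefl1, which encodes a protein related to Rap exchange factors, was 2.40-fold higher (139.8 ± 19.7 against 58.1 ± 7.94 CPM, adjusted p = 4.52e-07).

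Other genes among the 10 with the highest fold changes were Fbxl8, an F-box gene (4.11 against 1.02 CPM, log2 fold change 2.01), Sfmbt2, which encodes a Polycomb group protein (9.13 against 2.79 CPM, 1.71), and the imprinted gene Zdbf2 (14.9 against 6.12 CPM, 1.29). The neuregulin receptor gene Erbb4 was 1.94-fold higher (64.8 ± 10.8 against 33.5 ± 5.77 CPM, adjusted p = 6.12e-04) and the long noncoding RNA Tunar 1.97-fold higher (30.4 ± 3.02 against 15.4 ± 1.67 CPM, adjusted p = 6.86e-04). Prr16 had a log2 fold change of 0.95 and Ppl, which encodes the cytoskeletal linker periplakin, of 0.86. Among these genes, the adjusted p was 0.00310 for Sfmbt2, 0.00481 for Zdbf2, 0.0271 for Fbxl8 and 0.0274 for both Prr16 and Ppl. DESeq2 gave no adjusted p, and so no call, to these 5, since its independent filtering set them aside for their low level.

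The largest decreases were smaller. Afap1l1, which encodes an actin-associated protein, fell from 17.5 ± 3.02 to 7.91 ± 2.88 CPM (log2 fold change -1.14, adjusted p = 0.0149), Mamstr, which encodes a coactivator of MEF2 factors, from 11.4 ± 0.65 to 5.45 ± 1.34 CPM (-1.07, adjusted p = 0.0271), and Phldb2, whose product tethers microtubules at the cell cortex, from 10.4 ± 1.02 to 4.94 ± 1.17 CPM (-1.07, adjusted p = 0.0347). The scaffold gene Ahnak fell by 0.95 on the log2 scale (adjusted p = 0.00456), the guanine nucleotide exchange factor gene Arhgef15 by 0.88 (0.0344), the gamma-tubulin gene Tubg2 by 0.81 (0.0339), the splicing-related gene Cactin by 0.79 (0.0135), Trnp1 by 0.62 (0.0197) and the cilium-associated gene Erich3 by 0.60 (0.0135). Prpf38b, which encodes a splicing factor, was the most abundant of the named genes that fell, at 257 ± 17.1 against 399 ± 57.6 CPM (-0.64, adjusted p = 3.33e-04). Tubg2 lies near Ezh1 on chromosome 11. Afap1l1, Mamstr, Phldb2, Arhgef15 and Tubg2 likewise had no adjusted p and no call from DESeq2.

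**Figure D1:**
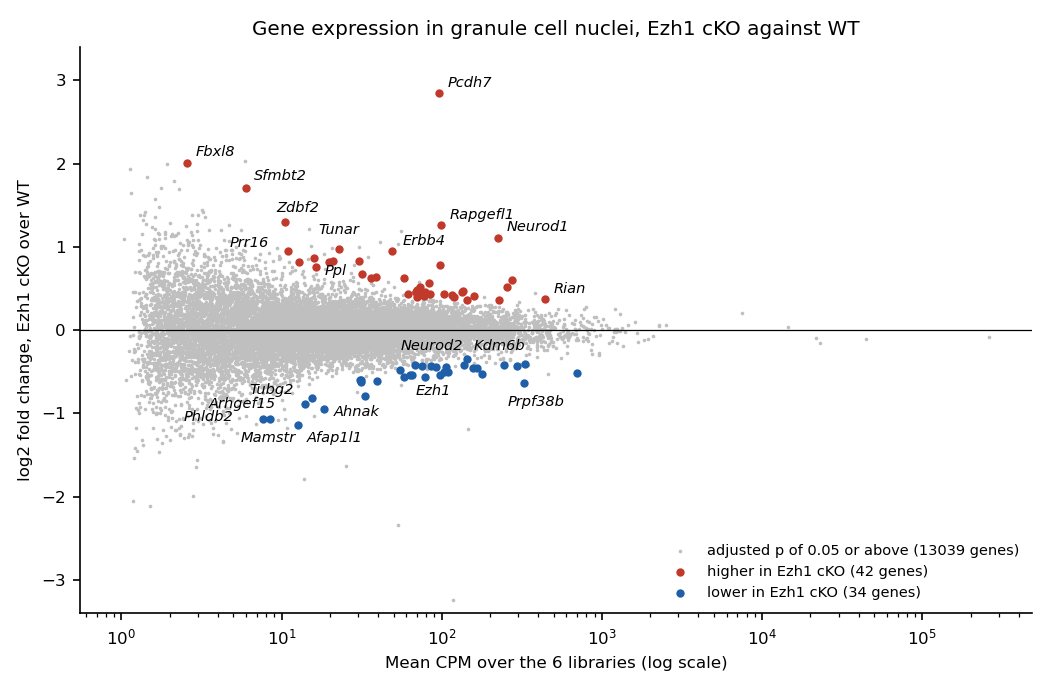
Each point is 1 of the 13115 tested genes, with its mean CPM over the 6 libraries on a log axis and its log2 fold change in Ezh1 cKO over WT; red points are the 42 genes called higher and blue points the 34 called lower. Pcdh7 stands apart at 2.85, and most called genes lie within a log2 fold change of 1 of zero.

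**Figure D2:**
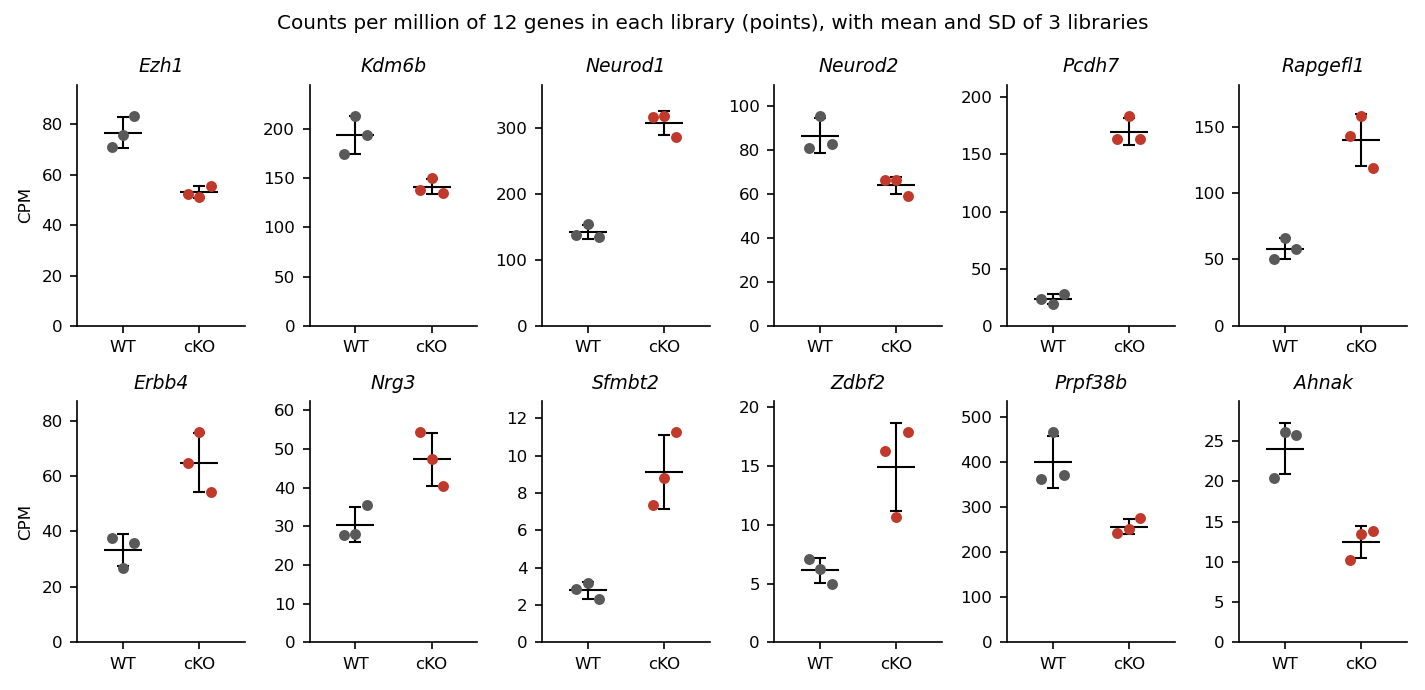
Points are the CPM of 12 genes in each of the 3 WT and 3 cKO libraries, and bars are the mean and SD of each genotype, on axes that start at zero. In each of these genes the libraries of the genotypes do not overlap, as for Pcdh7 (23.5 CPM on average in WT and 170 in cKO).

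In all, 42 genes were higher and 34 lower in cKO, 76 of 13115 tested (0.58%), and for all 76 the genotypes did not overlap. Over all tested genes 16.3% were separated in this way, where chance gives 10%. At an unadjusted p below 0.05 there were 1555 genes, where chance alone gives 656. The changes were small: the median absolute log2 fold change of the called genes was 0.54, and 6 higher and 3 lower genes lay beyond 2-fold. Scaling by library size alone gave 69 higher and 32 lower genes. The counts also depended on single libraries. They fell to 13 higher and 5 lower without WT replicate 2, to 10 and 3 without WT replicate 3 and to 10 and 4 without cKO replicate 1, and rose to 116 and 133 without WT replicate 1 and to 88 and 62 without cKO replicate 2. All 76 genes kept their direction in each of these fits. Pcdh7, Neurod1, Rapgefl1, Erbb4, Tunar and Prpf38b were called in every fit without a library, while each of the other called genes that the naming rule picked lost its call in at least 1.

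For 10621 genes (81.0%) the 95% interval lay within 2-fold, so a larger change was excluded gene by gene. The share followed the level: 97.6% of genes at 10 to 30 CPM and 99.4% of those above 100 CPM, but 70.6% at 3 to 10 CPM and 11.9% at 1 to 3 CPM.

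Of the PRC2 subunits, 12 were tested, and Ezh1 alone was called (2 were lower adjusted over the list alone, Ezh1 and Eed). Eed, the subunit that binds H3K27me3, was at 25.3 ± 2.66 CPM in cKO and 35.1 ± 2.49 CPM in WT (log2 fold change -0.47, SE 0.13, adjusted p = 0.105). Ezh2, which encodes the other catalytic subunit, had a log2 fold change of -0.10 with a 95% interval of -0.39 to 0.19, and Suz12 one of -0.07 (-0.29 to 0.16). The log2 fold changes of the rest were 0.09 for Jarid2, -0.19 for Aebp2, 0.23 for Phf1, 0.01 for Mtf2, 0.22 for Phf19, -0.06 for Rbbp4, -0.17 for Rbbp7 and -0.52 for Ezhip. Of 20 enzymes that methylate, demethylate or acetylate H3K27, H3K36, H3K4 or related sites, Kdm6b, which encodes a demethylase of H3K27me3, was called lower (141 ± 7.71 against 193 ± 19.4 CPM, -0.46, adjusted p = 0.00758), and it was also the 1 called adjusted over the list alone. Of 23 PRC1 subunits none was called by edgeR, DESeq2 or limma-voom, nor adjusted over the list alone, and 3 had an unadjusted p below 0.05. The smallest p values were those of Pcgf5 (log2 fold change 0.39, adjusted p = 0.213) and Cbx8 (0.52, adjusted p = 0.275).

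Hox genes, which Polycomb classically keeps silent, stayed low. None of 39 Hox genes passed the filter on low counts, and together they held 1.84 ± 0.96 CPM in WT and 2.04 ± 0.91 CPM in cKO. Of 127 developmental transcription factors 23 were tested, 11 with a positive and 12 with a negative log2 fold change (median -0.11). EdgeR and DESeq2 called 0 of them, 4 had an unadjusted p below 0.05, limma-voom called 1, Eomes, and 1 was higher and 2 lower adjusted over the list alone. DESeq2 could not call the members that its filtering set aside for their low level. The log2 fold change was 1.01 for Eomes, a factor of unipolar brush cells (20.5 ± 1.55 against 10.3 ± 4.92 CPM, adjusted p = 0.0868), and -1.56 for Foxd1 (1.49 ± 0.58 against 4.47 ± 1.68 CPM, adjusted p = 0.0881). Summed over the 166 Hox genes and developmental factors, the level was 402 ± 23.2 CPM in cKO and 423 ± 14.5 CPM in WT (ratio 0.950, exact permutation p = 0.2).

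Genes silent in WT were not switched on in cKO in this count. Of 6987 entries below 0.1 CPM in WT, 0 reached 0.5 CPM in each cKO library, and in the mirror direction 1 did, Gm7904 (5, 4 and 7 counts in WT and 1, 0 and 0 in cKO), named after its values were seen. With silence set below 0.3 CPM, 20 genes were gained and 19 lost. Of 10 tested cell cycle inhibitors and senescence genes none was called by any of the 3 tools, 2 had an unadjusted p below 0.05 and 1 was higher adjusted over the list alone, Rb1 (log2 fold change 0.39, adjusted p = 0.146). Bbc3 had a log2 fold change of -0.54 (adjusted p = 0.315).

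Among 29 mature granule cell markers, 1 was higher and 1 lower, also adjusted over the list alone. These were Neurod1, above, and its relative Neurod2, which fell from 86.4 ± 7.95 to 63.8 ± 3.98 CPM (log2 fold change -0.44, adjusted p = 0.0269). The median of the list was 0.03. Of 23 tested genes of granule cell progenitors and immature neurons 0 were called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, and 3 had an unadjusted p below 0.05, among them the hedgehog effector gene Gli1 (-0.56, adjusted p = 0.275) and Plxnb2 (-0.17, adjusted p = 0.393).

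Of the 25 lists tested, 3 passed the test against all other genes with the preset correlation, 7 had an unadjusted p below 0.05 there, and none passed with the estimated correlation or in fry's directional test (0 and 1 at an unadjusted p below 0.05). Fry's mixed test, which looks for change in either direction within a list, passed 6: mature granule cell markers (adjusted p = 2.83e-04), ribosomal protein genes (6.21e-04), PRC2 subunits (0.00319), stress genes (0.0213), imprinted genes (0.0343) and histone enzymes (0.0472). The PRC2 list holds the targeted gene Ezh1 itself, and the granule cell list holds the called Neurod1 and Neurod2. The histone enzyme list holds the called Kdm6b, and the imprinted list the called Zdbf2 and Rian. None of these lists was tested again without its called genes, so this does not show a change of any of them as a group. Immediate early genes, which neuronal activity induces within minutes, were lower (median -0.34, 15 of 19 negative, camera adjusted p = 0.0129, adjusted p = 0.652 with an estimated correlation). None of the 19 was called by any of the 3 tools, 6 had an unadjusted p below 0.05, and 2 were lower adjusted over the list alone, Junb (9.45 ± 4.80 CPM in WT and 4.33 ± 1.20 in cKO, adjusted p = 0.132) and Jun (23.9 ± 2.25 and 17.2 ± 1.71, adjusted p = 0.158). Their sum was 305.5, 416 and 362 CPM in the WT libraries and 317, 324 and 296 CPM in the cKO libraries, so WT replicate 1 lay among the cKO values. The list was not past the threshold without WT replicate 2 (adjusted p = 0.116) or cKO replicate 3 (0.0827).

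Voltage-gated ion channels were higher by a small amount (median 0.12, 29 of 40 positive, camera adjusted p = 0.0479, adjusted p = 0.652 with an estimated correlation). EdgeR called 0 of the 40, 10 had an unadjusted p below 0.05, and 4 were higher adjusted over the list alone. The calcium channel gene Cacna1e was at 871 ± 44.4 against 718 ± 36.1 CPM (0.28, adjusted p = 0.0539, called by DESeq2 and limma-voom), and the potassium channel gene Kcnh1 at 120.1 ± 2.97 against 99.7 ± 3.33 CPM (0.27, adjusted p = 0.143). Nuclear long noncoding RNAs were also higher in the median (0.18, 11 of 14 positive, camera adjusted p = 0.0479, adjusted p = 0.652 with an estimated correlation). Their summed level went the other way (55950 CPM in cKO against 57600 in WT, exact permutation p = 0.5). Meg3, Rian and Mirg, all positive, lie close together on chromosome 12. The 1 called member of the list was Rian (497 ± 49.5 against 385 ± 24.9 CPM, 0.37, adjusted p = 0.0214), and 2 were higher adjusted over the list alone. Rian (109603945 to 109661716) and the gene Rtl1 (109564900 to 109604418) share a short stretch, whose reads cannot be told apart. Without WT replicate 2, WT replicate 3, cKO replicate 1 or cKO replicate 3 neither the channels nor the noncoding RNAs were past the threshold (camera adjusted p of 0.0827 to 0.262), and without WT replicate 1 the noncoding RNAs were at 0.0578. With replicate number as a block the channels were at 0.103 and the noncoding RNAs at 0.0577, and without a filter on low counts both were at 0.0690.

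Other neuronal lists did not pass. Of 27 subunits of ionotropic glutamate and GABA-A receptors 17 were positive (median 0.12, camera adjusted p = 0.152), with 3 at an unadjusted p below 0.05 and 0 called by any tool or adjusted over the list alone. Grik1 had a log2 fold change of 0.68 (adjusted p = 0.244) and Grik3 of 0.26 (0.341). Of 49 clustered protocadherins, a family apart from Pcdh7, 30 were negative (median -0.05, camera adjusted p = 0.119), with the same counts of 3 and 0. This list passed without cKO replicate 2 (camera adjusted p = 0.0179). Pcdhb21 had a log2 fold change of -0.94 (adjusted p = 0.288) and Pcdhgb6 of -0.22 (0.341).

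**Figure D3:**
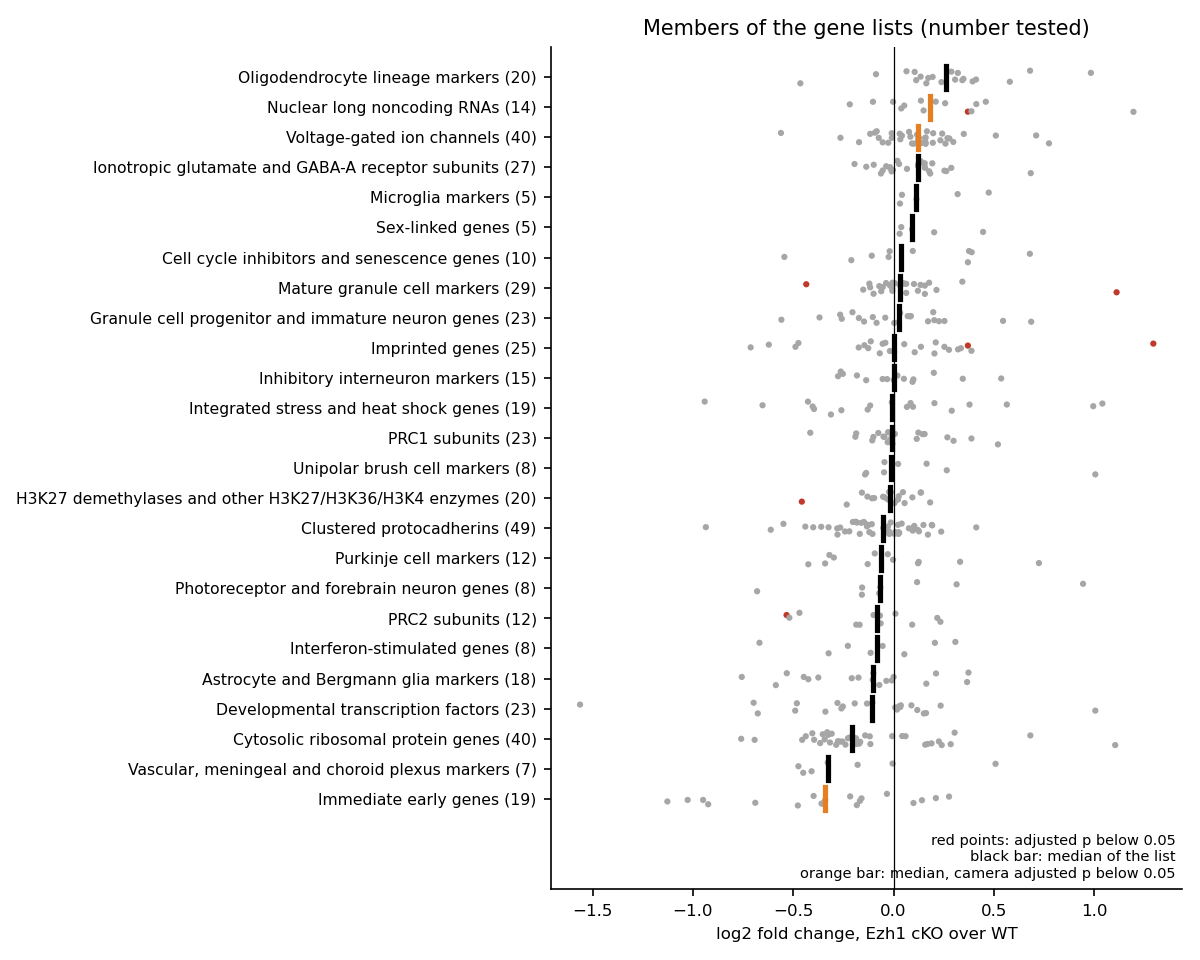
Points are the log2 fold changes (cKO over WT) of the tested members of 25 gene lists, red where the edgeR adjusted p was below 0.05; bars are list medians, orange for the 3 lists past the camera threshold with a preset correlation. Medians ran from -0.34 for immediate early genes to 0.26 for oligodendrocyte markers.

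Of 25 tested imprinted genes, 2 were higher, Zdbf2 and Rian, and 3 adjusted over the list alone. The list as a whole had a median of 0.00 (camera adjusted p = 0.366). Its summed level was higher in every cKO library than in every WT library (means of 14060 and 12660 CPM, exact permutation p = 0.1). Meg3 alone held 7983 and 6903 CPM of these means. Such a separation was not particular to this list. The sums of interferon-stimulated genes (ratio of cKO to WT 0.872), ribosomal protein genes (0.908) and PRC2 subunits (0.932) were separated too, all lower in cKO (exact permutation p = 0.1 for each). Of 19 stress and heat shock genes none was called by any tool, 6 had an unadjusted p below 0.05, and 2 were higher and 1 lower adjusted over the list alone. Hsp90b1 had a log2 fold change of 0.38 (adjusted p = 0.102) and Xbp1 of 0.56 (0.121). Of 8 interferon-stimulated genes none was called, 2 had an unadjusted p below 0.05, and 1 was lower adjusted over the list alone, Stat2 (-0.32, adjusted p = 0.0989). Irf9 stood at 0.31 (0.417). Of 40 cytosolic ribosomal protein genes none was called, and 29 were negative (median -0.21, camera adjusted p = 0.146). Rps6 had a log2 fold change of 1.10 (adjusted p = 0.340). The 5 tested sex-linked genes were not called, with wide intervals from the mixed libraries (Uty -3.20 to 4.10, Ddx3y -3.66 to 4.07).

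Markers of other cell types were present at low levels, and none of their 93 tested list entries was called by edgeR or DESeq2. Limma-voom called Eomes. DESeq2 could not call the members that its filtering set aside for their low level. The medians were -0.06 for 12 Purkinje cell markers (Homer3 -0.42, Foxp2 0.72), 0.00 for 15 inhibitory interneuron markers (Gad2 0.54, Kit -0.28), -0.01 for 8 unipolar brush cell markers (Eomes above), -0.10 for 18 markers of astrocytes and Bergmann glia (Slc1a2 0.37), 0.11 for 5 microglia markers (Inpp5d 0.47, P2ry12 0.32), -0.33 for 7 markers of vessels, meninges and choroid plexus (Bsg -0.18, Kcnj13 0.51) and -0.07 for 8 photoreceptor and forebrain neuron genes (Penk 0.31). Camera adjusted p-values were between 0.502 and 0.865 for these lists. The mean was of the other sign than the median for unipolar brush cell markers (0.14), photoreceptor and forebrain genes (0.03), stress genes (0.00) and PRC1 subunits (0.03, median -0.01), and camera took the sign of the mean for all but the stress genes, which it placed lower like their median of -0.01; for inhibitory interneuron markers it pointed lower though mean and median were 0.01 and 0.00. Of 20 oligodendrocyte markers 18 were positive (median 0.26; Mal 0.98, Cldn11 0.68), with an adjusted p of 0.366, and their sum ran from 333 to 537 CPM in WT and from 385 to 841 CPM in cKO. Without cKO replicate 2 this list passed (camera adjusted p = 2.62e-04).

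**Figure D4:**
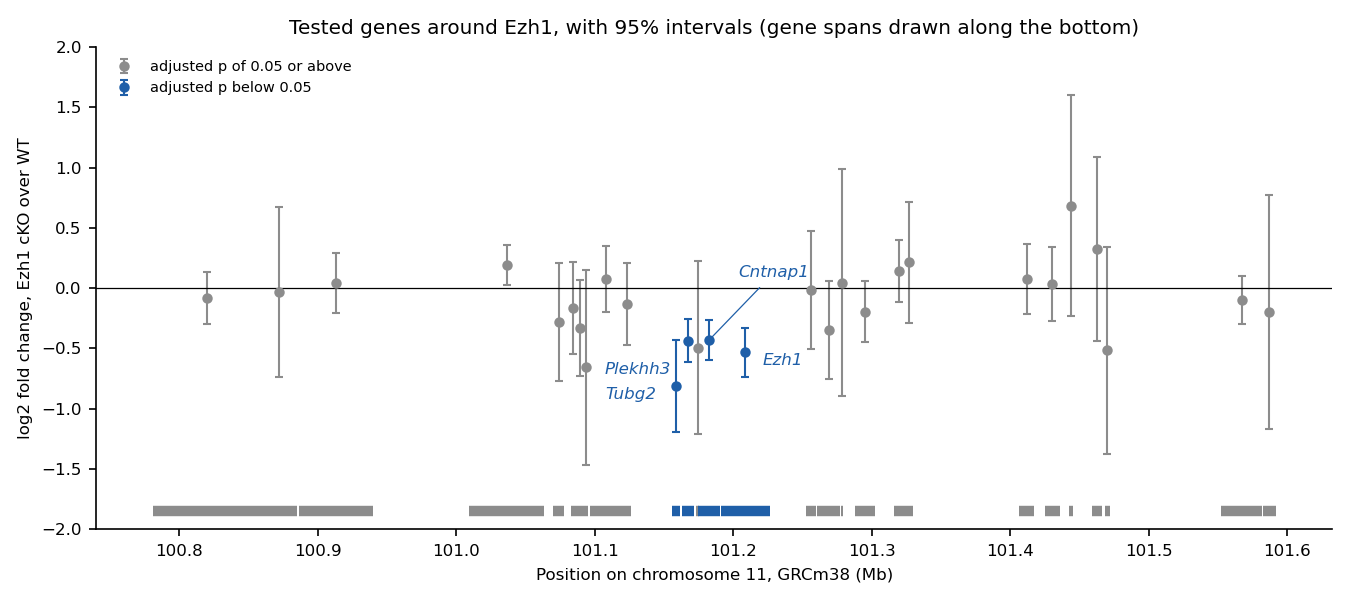
Points are the log2 fold changes (cKO over WT) of tested genes near Ezh1 by position on chromosome 11 (GRCm38, Mb), with 95% intervals, blue where the adjusted p was below 0.05; bars along the bottom are the gene spans. Ezh1 (-0.53), Cntnap1 (-0.43), Plekhh3 (-0.44) and Tubg2 (-0.81) lie close together and were all called lower, while Ccr10, between Plekhh3 and Cntnap1, was not called (-0.49, adjusted p = 0.636).

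Called genes were found on every autosome and the X chromosome, with 12 of the 76 on chromosome 11, and all 4 on the X chromosome (Phka2, Thoc2, Las1l and Rpgr) were lower. In the immediate neighbourhood of Ezh1, 3 genes were called besides Ezh1, all of them lower: Cntnap1, which encodes a protein of the axonal paranode (-0.43, adjusted p = 0.00672), Plekhh3 (-0.44, 0.0135) and Tubg2. These and the X-linked genes were named after their values were seen. Without chromosome 11, an alternative added after the data were seen, 38 higher and 24 lower genes were called.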

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

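All 76 called genes kept their direction in every alternative that tested them; without chromosome 11, 64 of them were tested. The 73 named genes other than Ezh1 had 1061 values under alternatives, of which 971 stayed on the same side of the threshold, 59 lost a call, 31 gained one and 0 changed direction with a call; 6 of 23 called genes kept their call throughout. RLE size factors, the filter of 1 CPM in 3 libraries, DESeq2 (45 higher, 41 lower) and limma-voom (44 and 33) gave counts within 1.5 times of the 42 and 34. DESeq2 shared 35 and 29 of those genes; the other 12 got no adjusted p from its independent filtering, among them 10 named genes, and are not in the counts of lost calls above. Library size alone gave 69 higher genes, the Y-linked covariate 73 higher and 65 lower (with all 76 among them), and an adjusted p below 0.1 gave 85 and 77. Without a filter on low counts there were 146 and 131: only 3 of the 201 added genes had been removed by the filter, and the median prior degrees of freedom of edgeR rose from 23.1 to infinity, with an infinite value for 94.3% of genes, whose own spread then no longer counted. With replicate number as a replicate block 49 and 41 genes were called, with 37 and 29 of the original calls among them. The deviations of same-numbered libraries correlated at 0.15, 0.01 and -0.04. WT replicate 1 correlated best with cKO replicate 1, also on autosomes alone (0.06). WT replicate 2 correlated best with cKO replicate 3, and WT replicate 3 with cKO replicate 2. So few correlations do not settle whether the numbers pair the samples. Leaving out each library in turn gave 10 to 116 higher and 3 to 133 lower genes and an Ezh1 log2 fold change of -0.58 to -0.47; some of the loss comes from testing 5 libraries instead of 6. Gene lists past the threshold numbered 3, against 0 with the estimated correlation, 0 by fry's directional test (6 by its mixed test), 1 with the block, 1 without a filter and 0 to 5 without a library. Silent genes gained numbered 1 by library size alone, 20 below 0.3 CPM and 3 to 12 without a library; those lost numbered 19, 0 with silence as 0 counts, and 2 to 11. The mean of log2(CPM + 0.1) over Hox genes and developmental factors differed by 0.0597 (exact permutation p = 0.8), opposite in sign to the difference of their sums (-21.2 CPM). Apart from those with a reason given, the causes were not tested. Leaving out the 4 entries with the most counts (44 and 34) and chromosome 11 (38 and 24) were chosen after seeing the data. Depth limits genes below 10 CPM most: their intervals were 0.60 wide on either side at 3 to 10 CPM and 0.96 at 1 to 3 CPM, in the median.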

Other observations

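The genes in the following 3 paragraphs were picked after their values were seen. At the imprinted Dlk1-Meg3 region of chromosome 12, Rtl1 was called higher with Rian (157.6 ± 13.9 against 113.5 ± 16.3 CPM, log2 fold change 0.47, adjusted p = 0.0184), and Meg3 (0.21, adjusted p = 0.0818) and Mirg (0.39, adjusted p = 0.291) were not called. Rtl1 (109564900 to 109604418) overlaps part of the far more abundant Meg3 (109540996 to 109571729) and a short stretch of Rian. With strand use not given, reads of the shared parts cannot be told apart, so these values may not be fully separate observations. Other imprinted transcripts stood at -0.02 (Peg3) and 0.14 (Kcnq1ot1). Of the receptor and ligand genes of the neuregulin family, Erbb4 was higher with its ligand gene Nrg3 (47.3 ± 6.88 against 30.4 ± 4.47 CPM, 0.64, adjusted p = 0.0209), and Nrg1 (0.31, adjusted p = 0.699) and Nrg2 (0.02, adjusted p = 0.955) were not called. Srrm4, which encodes a regulator of neuronal microexon splicing, was 1.52-fold higher (331 ± 22.7 against 219 ± 21.8 CPM, adjusted p = 2.23e-04) together with the noncoding gene Srrm4os that overlaps it (1.72-fold, adjusted p = 1.54e-05), whose reads cannot be told apart here. Its relative Srrm3 had a log2 fold change of -0.06 (adjusted p = 0.814).

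Other genes called higher were the sodium/calcium exchanger gene Slc8a1 (log2 fold change 0.41), the calcium pump gene Atp2b4 (0.63), the adenylyl cyclase gene Adcy8 (0.46) and the phosphodiesterase gene Pde4b (0.43), with adjusted p-values of 0.0255, 0.0126, 0.0215 and 0.0165; they were picked one by one and are not a tested group. Cep164 (-0.46), Cep131 (-0.50), Rpgr (-0.59), Cc2d2a (-0.42) and Erich3 (-0.60), which have roles in cilia or centrosomes, were called lower; they were picked from the calls, which were not tested for enrichment of such genes.

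Several genes differed between single libraries far more than between genotypes and were not called. Mapk6 had 4799 counts in WT replicate 3 and 135 to 200 in the other 5 libraries, and Mertk had 737 in WT replicate 3 and 77 to 90 elsewhere. Reep2 had 2024 and 2136 counts in WT replicates 2 and 3, 966 in cKO replicate 3 and 387 to 443 in the others. Snhg4 had 749, 1094 and 17 counts in the WT libraries and 8, 326 and 11 in the cKO libraries.

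The tests below were all chosen after the results were seen, except the count of splits, and the ciliary list was written before its genes were tested. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 42 genes higher and 34 lower, and the highest other split called 6 in a direction and 7 in all; thus 1 of the 10 gave as many higher genes and 1 of the 10 as many lower genes.

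Of 84 tested genes within 2 Mb of Ezh1, 3 were called. Among 10000 gene sets matched on expression, with the real set counted in, the share that held as many was 0.0101. The window was set around calls already seen, so chance stays open. Transcripts running on from Ezh1 into Cntnap1, which ends opposite it, would fall no more than Ezh1 itself, yet Cntnap1 fell 4.66 times as much per kb of exon (95% interval 1.54 to 7.78). The exon lengths were those of GENCODE, since the annotation used for counting is not given. The count of Ezh1 is over the whole gene, so the fall at its end next to Cntnap1 was not measured. Alleles linked to the modified Ezh1 allele could differ over a wider interval, and at 2 to 20 Mb 6 of 402 genes were called, including Neurod2 and Rapgefl1, against 0.52% elsewhere (odds ratio 2.88, 95% interval 1.02 to 6.67). Against the rest of chromosome 11, where 2 of 594 were called, the difference did not pass (Fisher p = 0.0671, genes taken as independent), and the 6 went both ways, 3 higher and 3 lower. An effect of the deletion itself on its neighbours also stays open, and neither was separated from an effect of Ezh1 loss.

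For the rise of Neurod1, a larger share of granule cell nuclei would raise the other granule cell markers alike, but their median log2 fold change was 0.0193 (SD 0.14), with the intervals of all 28 below that of Neurod1. Extra gene copies that span both of its neighbours, as a large transgene could bring, would need a like rise of both flanking genes. Their upper 95% limits did not pass 0.55 (Cerkl 0.32, Itprid2 -0.03). Cerkl was not called (adjusted p = 0.236), but its whole interval was positive (0.08 to 0.55). Copies that reach only part of the flanks were thus not excluded. Extra copies of Neurod1 alone, for example from a driver present in another dose, cannot be told apart from a change in its transcription, since counts per gene hold only the 2.16-fold difference. The biological explanation, a response to the loss of Ezh1, stays open as well.

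The counts of calls fell without WT replicate 2, WT replicate 3 or cKO replicate 1 (to 5, 3 and 4 lower and 13, 10 and 10 higher genes) and rose without WT replicate 1. WT replicate 1 was the lowest WT library in 27 of 34 genes called lower (79.4%), against 33.8% of genes not called (odds ratio 7.54, 95% interval 3.20 to 20.5, genes taken as independent). It was the highest WT library in 23 of 42 genes called higher (54.8%), against 33.7% of genes not called (odds ratio 2.38, 1.24 to 4.63). These genes were chosen by the calls, so this restates the pattern and does not decide its cause. Over all genes, chosen without regard to the calls, WT replicate 1 differed from cKO replicates 1, 2 and 3 by a chi-square per degree of freedom of 4.27, 4.97 and 4.16, and from WT replicates 2 and 3 by 5.01 and 4.55. This measure grows with depth, and WT replicates 2 and 3 were the deepest libraries. Pearson correlations of log2 CPM did not show the same order. They were 0.9805, 0.9805 and 0.9799 with the cKO replicates, and 0.9794 and 0.981 with WT replicates 2 and 3. WT replicate 1 was the WT library with high Xist, but cKO replicate 1 had that too. What sets this library apart, a technical difference or a difference between animals, was not identified.

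Of a list of ciliary genes written down to test for a wider fall, the 67 tested but not called had a median log2 fold change of -0.04 (26 positive, 41 negative), and the list did not pass (camera p = 0.114, p = 0.412 with an estimated correlation). For immediate early genes, none of 10000 lists matched on gene span and expression had a median as low. With the real list counted in, the share was 1e-04, the smallest the draws can give. For voltage-gated ion channels the share with a median as high, counted in the same way, was 0.0017. These draws treat genes as independent, and with an estimated correlation between genes neither list passed (camera adjusted p = 0.652 for both). Over all genes the log2 fold change rose weakly with gene span (Spearman correlation of 0.10 across genes, which are not independent).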
